A study of Mus musculus with 8 samples.

How the data were processed

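RNA-seq libraries were made from total RNA of mouse embryonic fibroblasts that expressed the adenoviral oncoprotein E1A and an activated Ras (HRasV12). Of these libraries, 4 came from wild-type cells and 4 from cells lacking the long noncoding RNA Neat1 (Neat1 null). Per the labels, 1 strain background was used, the RNA was isolated with a column kit, and libraries were made with a stranded TruSeq RNA kit. The labels give no sequencing date or batch, no sex, and no statement on whether the libraries of a group came from separate embryos or cultures, so the p-values measure the spread between these libraries. The Neat1 null libraries are not all from 1 embryo, since 3 were male and 1 was female by Xist and Y-linked genes. Pairs of libraries within a group differed by a chi-square per degree of freedom of at least 62.1, more than sampling noise of the reads.

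The authors deposited raw read counts per gene symbol, 1 file per library, which were used as deposited. The submitters' processing notes name CASAVA 1.8, STAR and DESeq2 and the mm10 build, without their roles or settings. The read counter, its strand setting and the gene annotation were not given in the sources used here. Each file held 23420 gene symbols. The last 2 entries of each file, reads outside annotated genes and reads ambiguous between genes, name no gene and were kept out of library sizes and tests. Reads outside genes made up 9.83% to 15.7% of the deposited counts in the wild-type libraries and 5.48% to 11.0% in the Neat1 null libraries. The ambiguous reads made up 1.09% to 1.22% and 1.34% to 1.76%. Mitochondrially encoded genes had no symbol matching the list fixed for them, so that list of 13 genes was not analysed here.

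Counts assigned to genes ranged from 31651625 to 37069334 per wild-type library and from 19651035 to 38950207 per Neat1 null library. Genes were kept with the filterByExpr function of edgeR 4.0.16 in R 4.3.3 (minimum count 10), which left 13316 genes, and library sizes were scaled with TMM factors. Each gene was tested with edgeR's quasi-likelihood F test (robust fit, 2-sided, genotype as the only term), and p-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Log2 fold changes are Neat1 null minus wild-type. The standard error of a log2 fold change was taken as its size divided by the square root of its F value. Values in CPM, counts scaled to a library size of 1e6, were computed from the deposited counts with the TMM factors and are given as mean ± SD of 4 libraries.

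Gene lists were fixed before the data were examined: 27 lists of pathways, complexes, positions, handling and quality signs and cell type markers, of which 25 had at least 3 tested members. Each was tested with camera (limma 3.58.1, preset correlation between genes of 0.01, 2-sided), adjusted over these 25 lists. The number of members past the threshold is given over all genes tested and adjusted over the list alone. Camera with an estimated correlation and the fry rotation test were run beside it. Genes named in the text follow a rule fixed at the same time: Neat1, Malat1, Trp53, Hras and Cdkn2a always, the 10 largest rises and the 10 largest falls among genes past the threshold with an average log2 CPM of at least 1 and no overlap between the groups, and from each list up to 4 called members with the smallest p. Unnamed gene models were to be left out of the 10 largest, and 0 had to be. Genes named outside this rule are said to be so.

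Single library measures were compared with exact 2-sided permutation tests over the 70 assignments of 8 libraries to groups of 4, which cannot give a p below 0.0286. Such tests were adjusted over a family of 10 measures. Neat1 was also compared in this way as log2(CPM + 1).

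Alternatives chosen before the data were examined were DESeq2-style (RLE) and upper-quartile size factors, no low-count filter, a filter of at least 1 CPM in 4 libraries, the fit without the robust option, DESeq2 1.42.0, each library left out in turn, the replicate number as a block, 1 surrogate variable (sva 3.50.0), an adjusted p under 0.01, an absolute log2 fold change of at least 1, X- and Y-linked genes left out, another pseudocount (0.1) and the other list tests. Alternatives chosen after the data were seen were a correction of each library for gene length and GC content (splines with 5 degrees of freedom, added as offsets), the sex of the library as a covariate, and the fit without Neat1 null libraries 1 and 3.

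Gene positions, exon lengths and GC contents came from the GENCODE M21 annotation of GRCm38, the assembly also called mm10. Of the symbols, 21777 matched directly, 1248 through a synonym and 395 not at all (98.3% matched). Coordinates are 1-based. Of 81 named genes, 25 share exon sequence with another annotated gene, 10 of them on the same strand and 18 on the other strand, so part of their counts is uncertain, as it is for the near-identical histone and ribosomal protein genes.

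The fit was tested on simulated counts drawn from the means, dispersions and library sizes of these 8 libraries, with 13227 genes tested and 50 genes changed at each fold. It recovered 6% of the genes changed 2-fold, 58% of those changed 4-fold, 94% of those changed 8-fold and 96% of those changed 16-fold, and 3.8% of its 132 calls were false. With a simulated length trend of the same slope in all libraries of a group, 39.8% of 221 calls were false, and 5.7% of 141 after the length and GC correction. The real slopes differed within groups, from -0.477 to 0.00710 in the Neat1 null libraries, and simulated genes were drawn independently. The shares of false calls may therefore not hold for the real data. Changes of 2-fold were therefore mostly not detectable with these libraries.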

Results

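RNA-seq read counts were available for 8 libraries of mouse embryonic fibroblasts transformed with E1A and HRasV12, 4 labelled wild-type and 4 labelled Neat1 null. The wild-type libraries held 34997707, 37069334, 32410368 and 31651625 counts assigned to genes, and the Neat1 null libraries 19651035, 32376822, 38950207 and 31416194. The comparison asks which genes differ in expression between transformed fibroblasts with and without Neat1, the noncoding RNA around which nuclear paraspeckles assemble, and which the series describes as a target of p53.

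Neat1 itself, a lincRNA on chromosome 19 (GRCm38, 5824708 to 5845478, minus strand), fell from 700 ± 488 CPM in wild-type to 8.06 ± 2.28 CPM in Neat1 null libraries (mean ± SD, n = 4 each). Its log2 fold change was -6.44 (SE 0.66, adjusted p = 0.000761, edgeR), and 1.15% of the wild-type mean remained. Every Neat1 null library lay below every wild-type library (exact permutation p = 0.0286, the smallest this design can give). The wild-type libraries differed among themselves by 9.59-fold, with 138, 588, 753 and 1320 CPM, against 6.92, 11.3, 7.90 and 6.12 CPM in the Neat1 null libraries. Neat1 was called in each fit that left out 1 library, with adjusted p-values up to 0.0177. Malat1, the nuclear RNA encoded next to it (5795690 to 5802672), had 774 ± 548 CPM in wild-type and 208 ± 254 CPM in Neat1 null libraries, a log2 fold change of -1.89 (SE 0.77) that did not pass the threshold (adjusted p = 0.0984). It passed without Neat1 null library 1, where the log2 fold change was -3.24 (adjusted p = 0.0352), the only 1 of 8 fits with a library left out that called it. After the length and GC correction the log2 fold change of Malat1 was -1.23 (adjusted p = 0.267).

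**Figure D1:**
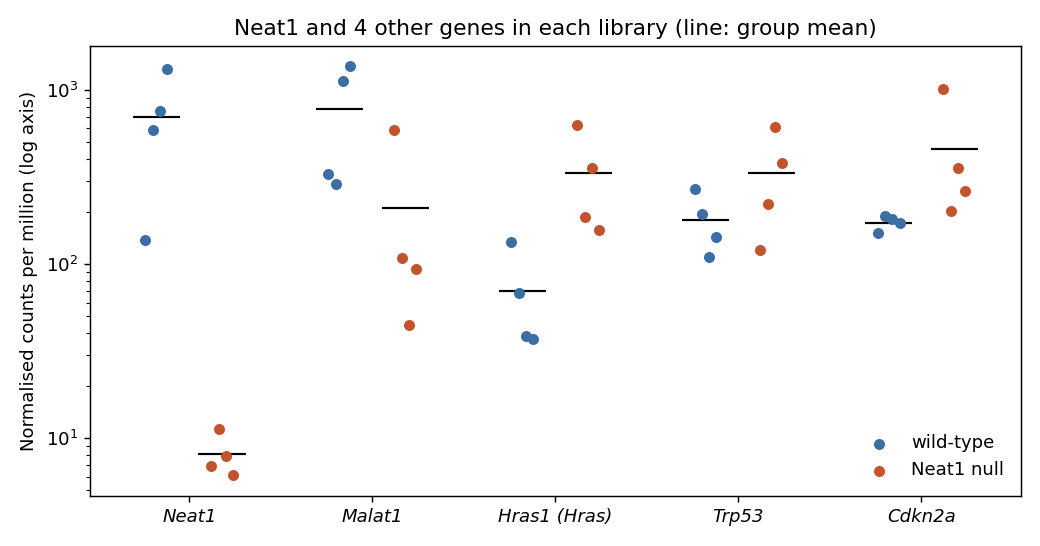
Normalised counts (CPM, log axis) of Neat1, Malat1, Hras1, Trp53 and Cdkn2a in each of the 4 wild-type and 4 Neat1 null libraries, with the group mean as a line. Neat1 lies at 138 to 1320 CPM in wild-type and at 6.12 to 11.3 CPM in Neat1 null libraries, and the ranges of Hras1 do not overlap either.

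The oxidative phosphorylation, histone, cholesterol synthesis, cell cycle and glycolysis lists stood higher in Neat1 null libraries, each with an adjusted p of 0.608 with an estimated correlation. Of 13316 genes tested, 2356 (17.7%) passed the threshold, 1328 of them higher and 1028 lower in Neat1 null libraries, and 2353 of these changed by at least 1 on the log2 scale. The 2 groups did not overlap for 3015 genes (22.6%). By chance a single gene would do so in 2.86% of assignments. Genes vary together and this share was not counted in other splits, so the excess was not tested. With upper-quartile factors the split was 1036 higher and 1428 lower, as the median log2 fold change of all genes moved from -0.06 to -0.239. Most adjusted p-values lay close to the threshold: the number of calls was 18 without wild-type library 3, 11 without wild-type library 4, 13 without Neat1 null library 3 and 7 without Neat1 null libraries 1 and 3 (chosen after the data were seen). With any 1 library left out, 0 of the 2356 calls changed sign. Neat1, Gabra2, the histone gene Hist3h2a (log2 fold change 2.92, SE 0.40) and the transcription factor gene Tbx20 (log2 fold change -2.84, SE 0.41) were called with each of the 8 libraries left out. The last 2 are named for that, after their values were seen.

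The libraries also differed in ways other than Neat1. By Xist against 4 Y-linked genes, the 4 wild-type libraries were female, Neat1 null libraries 1, 2 and 4 were male and Neat1 null library 3 was female. Ribosomal protein genes took 6.36 ± 0.448% of counts in wild-type and 14.3 ± 7.76% in Neat1 null libraries (exact permutation p = 0.0286, adjusted 0.0408 over 10 measures), with 25.1% in Neat1 null library 1. That library also held 5.23% of its counts on the ribosomal RNA gene Rn45s, against 0.457% to 0.596% in the other Neat1 null and 0.138% to 0.939% in the wild-type libraries. On the first principal component, 52.5% of the variance, the genotypes did not overlap (exact permutation p = 0.0286, adjusted 0.0408), and Neat1 null libraries 1 and 3 lay farthest from wild-type. Wild-type library 1 (-17.2) and Neat1 null library 2 (16.9) lay nearest each other across the genotypes. In log2 CPM, wild-type library 1 correlated more with Neat1 null libraries 2 and 4 (Pearson r 0.962 and 0.949) than with the other wild-type libraries (0.911 to 0.929).

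**Figure D2:**
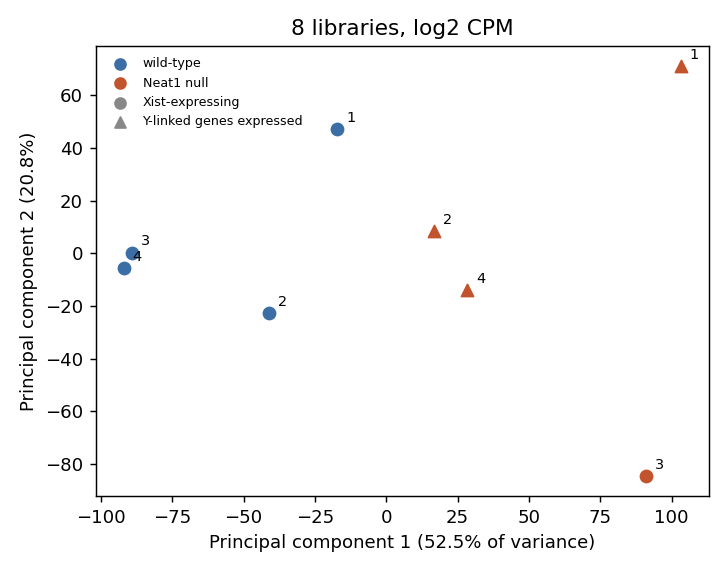
The 8 libraries on the first (52.5% of variance) and second (20.8%) principal components of log2 CPM, coloured by genotype, numbered by replicate, with circles for libraries that expressed Xist and triangles for those that expressed Y-linked genes. All 4 wild-type libraries lie at negative and all 4 Neat1 null libraries at positive values of the first component.

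Called rises lay mostly in shorter genes and called falls in longer genes. Among the 10% of genes with the shortest exon sequence (median 1346 bases) 400 genes rose and 14 fell, with a median log2 fold change of 0.88. Among the 10% with the longest (median 12556 bases) 8 rose and 273 fell, with a median of -0.69. Across 13206 genes, which are not independent replicates, Spearman's rho between length and log2 fold change was -0.409. For each library, the deviation of log2 CPM from the gene's mean over all libraries was fitted on log2 length. The slope was 0.209 ± 0.0517 per doubling of length in wild-type and -0.209 ± 0.226 in Neat1 null libraries (n = 4 each, exact permutation p = 0.0286, adjusted 0.0408). The 2 group means mirror each other by construction, so only their difference of -0.419 carries information. After each library was corrected for gene length and GC content, 1665 genes passed the threshold, 1018 higher and 647 lower, and 1236 of the 2356 genes remained among them.

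**Figure D3:**
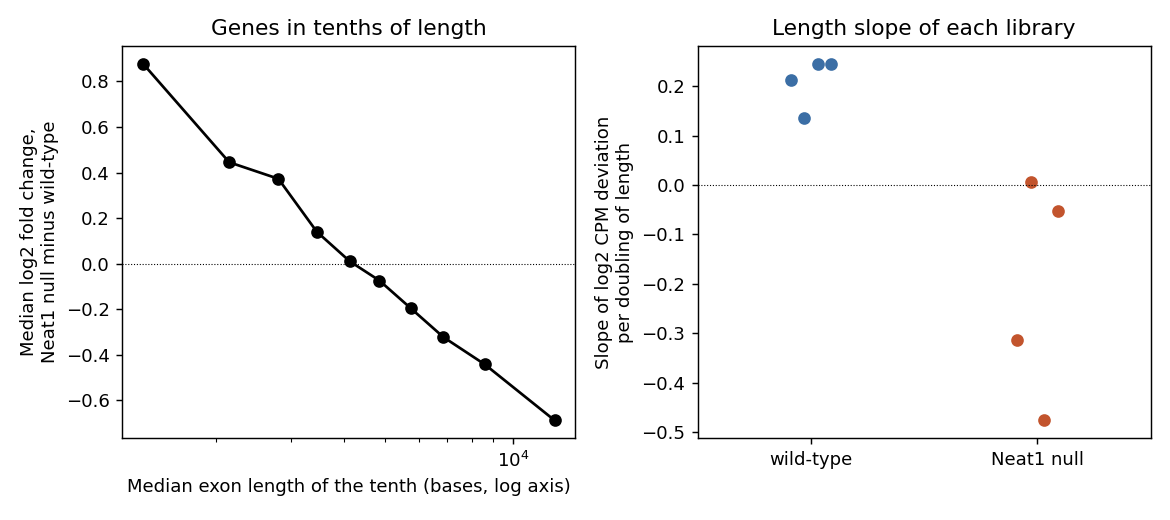
Left, the median log2 fold change (Neat1 null minus wild-type) of genes in 10 bins of exon length (bases, log axis), which goes from 0.88 in the shortest to -0.69 in the longest bin. Right, each library's slope of log2 CPM deviation from the mean of all libraries per doubling of gene length, positive in the 4 wild-type libraries and lower in each of the 4 Neat1 null libraries.

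Among called genes with an average log2 CPM of at least 1 and groups that did not overlap, the largest falls after Igsf1 were those of Cntn1, Gabra2 and Neat1. Gabra2 and Gabra3, subunits of the GABA-A receptor, had log2 fold changes of -6.75 (SE 0.81, adjusted p = 0.00278) and -4.65 (SE 0.83, adjusted p = 0.0180), from 5.64 ± 3.90 and 7.02 ± 6.75 CPM in wild-type to 0.0538 ± 0.0269 and 0.270 ± 0.0712 CPM in Neat1 null libraries. Cntn1, a contactin of the neuronal surface, fell by 6.81 (SE 1.09), and Slitrk4, a transmembrane protein that acts at synapses, fell by 5.88 (SE 0.82). Igsf1, an immunoglobulin superfamily membrane protein, fell by 7.59 (SE 1.42), from 15.2 ± 23.0 CPM, where wild-type library 4 alone had 49.5 CPM. Without that library the log2 fold change of Igsf1 was -5.59 (adjusted p = 0.0240). Fxyd6, a regulator of the sodium pump, Prokr2, the prokineticin receptor, Rufy4 and Egflam had log2 fold changes of -5.01 (SE 1.08), -4.66 (SE 0.98), -4.95 (SE 0.98) and -4.77 (SE 1.01). The calls of these genes except Neat1 and Gabra2 ended without Neat1 null library 3 (adjusted p = 0.0646 to 0.0650), and those except Neat1, Gabra2 and Slitrk4 without wild-type library 3 (0.0556 to 0.0670). Those of Fxyd6, Rufy4, Egflam, Prokr2 and Gabra3 also ended without wild-type library 4 (0.0584 to 0.0684). In that fit Cntn1, Fxyd6, Rufy4 and Gabra3 had log2 fold changes of -6.01, -4.26, -4.11 and -3.97, and without wild-type library 3 Egflam had -3.77. Larger falls were those of Cntn1 and Slitrk4 without Neat1 null library 4 (-8.93 and -6.49) and of Prokr2 without Neat1 null library 2 (-5.57).

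Neat1 null library 1 held the highest value of each of the 10 largest rises under the same limits. Atp5e, the epsilon subunit of ATP synthase, had a log2 fold change of 4.75 (SE 1.23, adjusted p = 0.0291), from 63.4 ± 11.5 CPM in wild-type to 1706 ± 2889 CPM in Neat1 null libraries, where library 1 had 6031 CPM. Without library 1 the log2 fold change was 2.05 (adjusted p = 0.0352). Ndufb7, a subunit of respiratory complex I, and Mrpl52, a mitochondrial ribosomal protein, rose by 3.59 (SE 0.84) and 3.47 (SE 0.97) and by 1.94 and 1.37 without library 1. Tmem223 rose by 3.55 (SE 0.69), the linker histone gene Hist1h1e by 3.95 (SE 1.02) and the histone H2B gene Hist3h2ba by 3.62 (SE 0.70). Tnnt1, a slow muscle troponin gene, rose by 4.46 (SE 1.06) from 0.183 ± 0.0966 CPM, the neuropeptide gene Npw by 4.16 (SE 1.15), Nr2c2ap by 4.13 (SE 1.09) and the microRNA gene Mir682 by 3.67 (SE 0.94). Mir682, of 96 bases, shares exon sequence with the processed pseudogene Gm4149 on the same strand, so its counts may not come from the microRNA. Without library 1, Npw, Hist1h1e and Mir682 had log2 fold changes of 1.87, 1.46 and 1.74 and no longer passed (adjusted p = 0.0744, 0.0965 and 0.0770). In that fit Tnnt1, Nr2c2ap and Tmem223 had 2.29, 1.89 and 2.64. The calls of all 10 ended without wild-type library 3 (adjusted p = 0.0589 to 0.115), wild-type library 4 (0.0645 to 0.142) or Neat1 null library 3 (0.0646 to 0.0659). Those of Atp5e, Npw, Nr2c2ap, Hist1h1e, Mir682 and Mrpl52 also ended without wild-type library 2 (0.0509 to 0.0854), and those of Npw and Mrpl52 without wild-type library 1 (0.0694 and 0.0586). With the length and GC correction the calls of Npw (2.47, adjusted p = 0.0650), Mir682 (1.53, 0.0952), Mrpl52 (2.33, 0.0601) and Hist1h1e (3.33, 0.0506) ended. Tmem223 and Hist3h2ba then had 2.22 and 2.44 and stayed called (adjusted p = 0.0345 and 0.0362).

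Among nuclear genes of oxidative phosphorylation, 18 of 30 tested members were higher in Neat1 null libraries and 0 lower (23 adjusted over the list alone), with a median log2 fold change of 1.65. The list stood above other genes (camera adjusted p = 4.57e-10, adjusted p = 0.608 with an estimated correlation). Cox4i1 of complex IV rose by 2.37 (SE 0.51), from 248 ± 52.1 to 1278 ± 825 CPM, Sdhb of complex II by 1.83 (SE 0.40), and Ndufs3 and Ndufb8 of complex I by 2.10 (SE 0.47) and 2.06 (SE 0.48). After the length and GC correction 11 members passed and the median was 1.12. Cox4i1, Sdhb, Ndufs3 and Ndufb8 then had log2 fold changes of 1.47, 1.30, 1.53 and 2.21, all still called. Without wild-type library 3, wild-type library 4 or Neat1 null library 3, 0 members passed (these 4 genes at 0.0687 to 0.0715, 0.0684 to 0.0693 and 0.0646), while the list median stayed between 1.26 and 1.89 with any 1 library left out. Ndufb8 had 1.39 without Neat1 null library 3. Without Neat1 null libraries 1 and 3 the list median was 0.74.

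All 12 tested members of the 24 listed replication-dependent histone genes rose, also 12 adjusted over the list alone, with a median log2 fold change of 3.67 (camera adjusted p = 6.07e-10, adjusted p = 0.608 with an estimated correlation). The linker histone gene Hist1h1c rose from 9.86 ± 6.59 to 71.6 ± 23.9 CPM, a log2 fold change of 2.86 (SE 0.48, adjusted p = 0.0180), and Hist1h2bc from 5.68 ± 3.42 to 28.7 ± 6.71 CPM, a log2 fold change of 2.34 (SE 0.45, adjusted p = 0.0180). Hist1h4b and Hist1h3a, with 0.998 ± 0.904 and 1.23 ± 1.29 CPM in Neat1 null libraries, rose by 4.03 (SE 0.84) and 4.36 (SE 1.02), and by 3.26 and 3.39 without Neat1 null library 1. Hist1h4b had 4.80 without wild-type library 1 and Hist1h3a 4.98 without wild-type library 2. Each had 9 counts over all wild-type libraries together, so both passed the count filter only through the Neat1 null libraries. Listed members low in both groups were not tested. The 12 of 12 rises, the median and the list test may therefore be inflated by the filter. These short genes have near-identical copies and mostly low counts, and most, not all, transcripts of such genes lack poly(A) tails. After the length and GC correction 6 members passed and the median was 2.84, without Hist1h3a (adjusted p = 0.0504). Leaving out wild-type library 3, wild-type library 4 or Neat1 null library 3 left 1 (Hist1h1c), 0 and 0 members past the threshold, and leaving out Neat1 null library 1 left 7, with the median between 2.63 and 4.22.

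Among cholesterol synthesis genes, 7 of 23 tested members were higher and 0 lower (14 adjusted over the list alone), with a median log2 fold change of 0.97 (camera adjusted p = 4.51e-05, adjusted p = 0.608 with an estimated correlation). Fdps, farnesyl diphosphate synthase, rose from 65.1 ± 6.71 to 264 ± 146 CPM, a log2 fold change of 2.02 (SE 0.40), and the mevalonate pathway enzymes Mvd, Mvk and Pmvk by 1.87 (SE 0.40), 1.89 (SE 0.42) and 1.76 (SE 0.40). Here the length and GC correction left 10 members higher and a median of 1.09. Mvd, Mvk and Pmvk then had smaller log2 fold changes of 1.12, 1.37 and 0.99, and Fdps had 2.04, all still called. Among glycolysis and hypoxia genes, 5 of 27 rose and 1 fell (9 adjusted over the list alone), with a median of 0.34 (camera adjusted p = 0.0336, adjusted p = 0.608 with an estimated correlation). Lactate dehydrogenase A (Ldha) rose from 592 ± 191 to 2986 ± 1430 CPM, a log2 fold change of 2.33 (SE 0.49), triosephosphate isomerase (Tpi1) by 2.28 (SE 0.51) and phosphofructokinase (Pfkl) by 1.74 (SE 0.42). The enolase gene Eno2 fell by 1.73 (SE 0.45). The glycolysis list was no longer called without wild-type library 1 (adjusted p = 0.146) or Neat1 null library 2 (adjusted p = 0.0807). Its median was 0.67 after the length and GC correction (5 higher, 1 lower) and 0.53 without Neat1 null library 1 (10 higher, 1 lower). Of the 30 cell cycle genes 5 rose and 0 fell (5 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 0.000330, adjusted p = 0.608 with an estimated correlation). They included Cdc20, the activator of the anaphase-promoting complex (1.87, SE 0.46), the survivin gene Birc5 (1.89, SE 0.51), thymidylate synthase (Tyms, 1.58, SE 0.43) and the replicative helicase gene Mcm5 (1.85, SE 0.55). Without wild-type library 3, wild-type library 4 or Neat1 null library 3, 0 members of these 3 lists passed (the genes named here at 0.0607 to 0.110, 0.0684 to 0.112 and 0.0646 to 0.116). Mcm5 was also lost without wild-type library 2 (0.0537) and Birc5 without Neat1 null library 1 (1.26, adjusted p = 0.0569). Of the cell cycle genes 3 passed after the length and GC correction and Cdc20 did not (1.24, adjusted p = 0.0774). Tpi1 and Mcm5 had log2 fold changes of 1.68 and 1.21 without Neat1 null library 3.

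**Figure D4:**
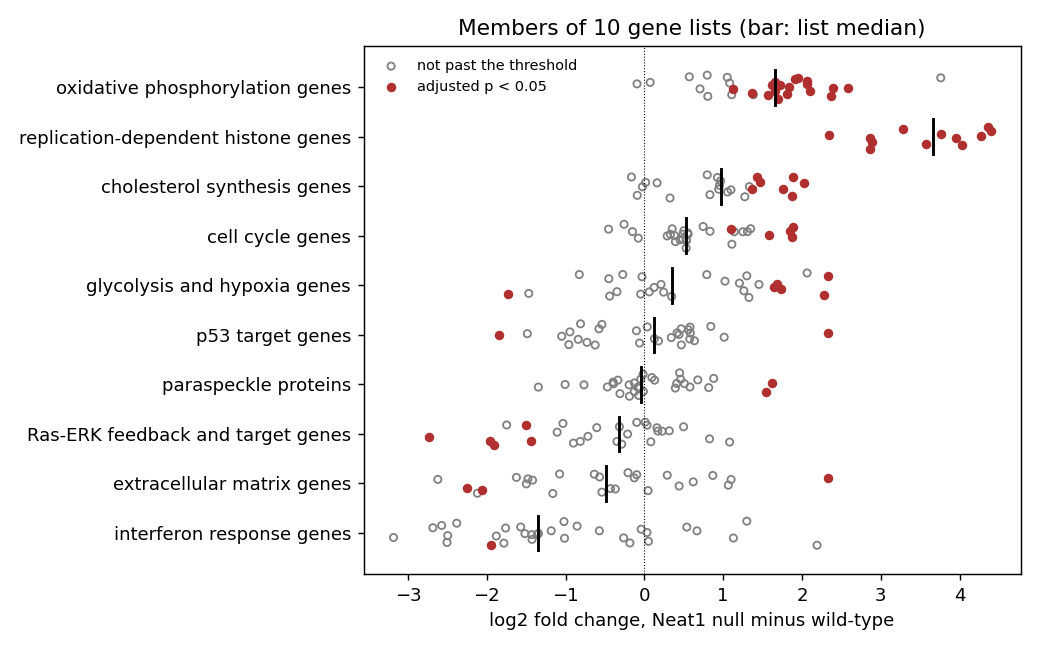
Log2 fold change (Neat1 null minus wild-type) of each tested member of 10 gene lists, filled where the adjusted p was under 0.05, with the list median as a bar. The histone list has its median at 3.67 and the oxidative phosphorylation list at 1.65, and the p53 target and paraspeckle lists centre near 0.

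The p53 target list was not called in a common direction. Of 29 tested p53 target genes 1 rose and 1 fell (2 adjusted over the list alone), the median log2 fold change was 0.13 and the mean -0.03, and the test, whose direction was down, gave an adjusted p of 0.858. The fry test for changes in either direction gave an unadjusted p of 0.0127 for it. That does not set the p53 list apart. The same test gave 0.00142 for Hox genes and 0.00192 for fibroblast markers, and 0.426 for interferon response genes. Over all genes tested, 17.7% were called. The apoptosis gene Bax rose by 2.33 (SE 0.55, adjusted p = 0.0190), from 155 ± 78.5 to 777 ± 547 CPM, and by 1.39 after the length and GC correction, where it no longer passed (adjusted p = 0.0654). Trp53inp1 fell by 1.85 (SE 0.52, adjusted p = 0.0288), and after the correction by 1.28 (adjusted p = 0.0596). Trp53 itself had 179 ± 69.6 CPM in wild-type and 333 ± 214 CPM in Neat1 null libraries (log2 fold change 0.90, SE 0.48, adjusted p = 0.189), and Cdkn2a, which encodes p16 and p19Arf, had 172 ± 16.7 and 456 ± 374 CPM (1.40, SE 0.48, adjusted p = 0.0541). With 1 library left out, the log2 fold change of Trp53 ranged from 0.44 to 1.17, and 0 of these 8 fits called it. Cdkn2a passed without Neat1 null library 2 (adjusted p = 0.0270) or 4 (0.0416). Without Neat1 null library 1, which had 1009 CPM against 200 to 354 in the others, its log2 fold change was 0.65 (adjusted p = 0.172), and after the length and GC correction 0.43 (adjusted p = 0.445). Among paraspeckle proteins, 2 of 31 rose and 0 fell (2 adjusted over the list alone): Nudt21, a cleavage factor subunit, by 1.55 (SE 0.34) and Rbm14 by 1.62 (SE 0.44). The list had a median of -0.05 and a mean of 0.08, and its test, whose direction was up, gave an adjusted p of 0.478. Its median was 0.41 after the length and GC correction, with 4 members higher and an adjusted p of 0.0693. Of 17 tested genes next to Neat1 on chromosome 19, 1 rose (1 adjusted over the list alone), Ap5b1 by 2.15 (SE 0.48, adjusted p = 0.0183), with an adjusted p of 0.102 for the list. The median of these neighbours was 0.67 with all libraries and 0.14 without Neat1 null library 3. The calls of Bax, Trp53inp1, Nudt21, Rbm14 and Ap5b1 ended without wild-type library 3 (adjusted p = 0.0687 to 0.0926), wild-type library 4 (0.0684 to 0.0956) or Neat1 null library 3 (0.0646 to 0.0903). Without the last, Ap5b1 had 1.44. The call of Trp53inp1 also ended without Neat1 null library 1 (0.0604).

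Hras, listed as Hras1 in the files (chromosome 7, 141189105 to 141194005, minus strand), rose from 69.6 ± 45.5 CPM in wild-type to 333 ± 218 CPM in Neat1 null libraries (log2 fold change 2.26, SE 0.53, adjusted p = 0.0190). The wild-type libraries had 134, 68.0, 38.7 and 37.2 CPM and the Neat1 null libraries 632, 187, 356 and 157 CPM. All of these cells carry the HRasV12 construct, and its reads were not separated from those of the endogenous gene. Without wild-type library 3, wild-type library 4 or Neat1 null library 3 the log2 fold change was 2.06, 2.05 and 2.23, no longer past the threshold (adjusted p = 0.0714, 0.0704 and 0.0650). Of the 27 feedback and target genes of Ras-ERK signalling 0 rose and 5 fell (6 adjusted over the list alone), with a median of -0.32 (camera adjusted p = 0.0552, adjusted p = 0.608 with an estimated correlation, and 0.000777 with the preset correlation after the length and GC correction). The list was called lower without wild-type library 2 (adjusted p = 0.0344), Neat1 null library 1 (0.0389) or Neat1 null library 4 (0.0424). With 1 library left out its median ranged from -0.54 (without Neat1 null library 4) to -0.18 (without wild-type library 1). The EGF-family ligands Ereg and Areg fell by 2.73 (SE 0.54) and 1.90 (SE 0.41). Hmga2, an architectural chromatin protein, fell by 1.97 (SE 0.49), from 953 ± 433 to 244 ± 106 CPM, and the transcription factor gene Etv1 by 1.50 (SE 0.42), by 0.44 after the correction (adjusted p = 0.397). Ereg, Areg, Hmga2 and Etv1 were no longer called without wild-type library 3 (0.0589 to 0.105), wild-type library 4 (0.0682 to 0.109) or Neat1 null library 3 (0.0646 to 0.0743).

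Several lists of stromal and stress genes held few called members and were not called as lists with all libraries. Of 26 extracellular matrix genes 1 rose and 2 fell (3 adjusted over the list alone, list adjusted p = 0.467). The collagen genes Col6a1 and Col12a1 fell by 2.25 (SE 0.57) and 2.06 (SE 0.57), and Timp1, an inhibitor of matrix metalloproteinases, rose by 2.33 (SE 0.53). In the inflammatory and secretory list 2 of 14 fell (2 adjusted over the list alone, list adjusted p = 0.180), the adhesion molecule gene Vcam1 by 2.91 (SE 0.63) and stromelysin (Mmp3), with a log2 fold change of -3.38 (SE 0.92). Among 31 interferon response genes 1 fell (0 adjusted over the list alone), Dhx58 by 1.94 (SE 0.62), the list median being -1.34 (adjusted p = 0.354). Wild-type library 1 had 48.9 CPM of Dhx58 and the other wild-type libraries 7.52 to 10.9. Without it the list median was 1.86, with 2 members higher and 0 lower, and Dhx58 had -0.90. Without Neat1 null library 1 the list was called lower (median -2.09, adjusted p = 0.0264 with the preset correlation). With all libraries it had an adjusted p = 0.843 with an estimated correlation. In the integrated stress response list 1 of 24 rose, the serine synthesis gene Phgdh by 2.14 (SE 0.54), and 2 fell, Aldh1l2 by 1.73 (SE 0.46) and Vldlr by 1.86 (SE 0.58), 3 adjusted over the list alone (list adjusted p = 0.124). Of 16 immediate early and heat shock genes 3 rose and 1 fell (6 adjusted over the list alone, list adjusted p = 0.0773). Ier2 rose by 2.28 (SE 0.47), Atf3 by 2.44 (SE 0.60) and Nr4a1 by 1.85 (SE 0.47), and Klf4 fell by 1.85 (SE 0.45). The contractile list had 1 of 22 higher (0 adjusted over the list alone, list adjusted p = 0.303), Csrp1 by 1.61 (SE 0.52). Neat1 null library 3 had 918 CPM of Csrp1 against 207 to 231 in the others, and without it the log2 fold change was 0.79 (adjusted p = 0.153). DNA repair had 1 of 29 higher, Ercc1 by 1.40 (SE 0.38), and 1 lower, Prkdc by 1.46 (SE 0.42), 2 adjusted over the list alone (list adjusted p = 0.50). The named calls of these lists ended without wild-type library 3 (0.0607 to 0.134), wild-type library 4 (0.0584 to 0.127) or Neat1 null library 3 (0.0646 to 0.153), except Nr4a1 without the last. Calls were also lost without wild-type library 1 (Dhx58 0.207, Csrp1 0.0742) or wild-type library 2 (Aldh1l2 0.0515, Vldlr 0.0641, Ercc1 0.0550). Others were lost without Neat1 null library 1 (Dhx58 0.0612, Mmp3 0.0514, Aldh1l2 and Vldlr 0.0502, Prkdc 0.0558) or Neat1 null library 4 (Dhx58 0.0729, Vldlr 0.0779). Vcam1 and Col6a1 had -2.09 and -1.54 without wild-type library 3, Mmp3 had -4.48 without Neat1 null library 4 and Col12a1 -2.69 without Neat1 null library 1. The inflammatory list was called lower without wild-type library 2 (0.0308) and after the length and GC correction (0.0255). The integrated stress response list was called higher without wild-type library 2 (0.0308) or Neat1 null library 1 (0.00867), and the immediate early list without wild-type library 3 (0.0446), Neat1 null library 1 (0.0177) or Neat1 null library 3 (0.00819). These calls used the preset correlation. With all libraries the inflammatory, integrated stress response and immediate early lists had adjusted p = 0.608, 0.651 and 0.608 with an estimated correlation. The length and GC correction ended the calls of Timp1 (1.42, adjusted p = 0.0814), Col12a1 (-1.31, 0.104), Vcam1 (-1.90, 0.0601), Dhx58 (-2.08, 0.0676), Csrp1 (0.93, 0.136), Vldlr (-1.01, 0.257), Prkdc (-0.63, 0.138), Atf3 (2.10, 0.0518) and Nr4a1 (1.83, 0.0554). Ier2 had 1.42 after it and stayed called (adjusted p = 0.0469).

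Developmental lists were similar. Of 22 imprinted genes 0 rose and 3 fell (3 adjusted over the list alone, list adjusted p = 0.303), Peg3 by 1.63 (SE 0.51), the receptor gene Igf2r by 1.40 (SE 0.44) and Plagl1 by 1.48 (SE 0.47). None of the imprinted genes passed after the length and GC correction (0), with Peg3 at -0.94 (adjusted p = 0.138), Igf2r at -1.02 (0.0851) and Plagl1 at -1.02 (0.0889). Of 36 Hox genes 1 fell (0 adjusted over the list alone), Hoxa13 by 2.17 (SE 0.60), and the list gave an adjusted p of 0.303 (adjusted p = 0.651 with an estimated correlation). The length- and GC-corrected fit gave 0.000154 with the preset correlation, with a median of -0.66. The calls of Peg3, Igf2r, Plagl1 and Hoxa13 ended without wild-type library 3 (0.0849 to 0.160), wild-type library 4 (0.0890 to 0.112) or Neat1 null library 3 (0.0667 to 0.0869). Single ones ended without wild-type library 1 (Plagl1 0.0586), wild-type library 2 (Peg3 0.0640, Igf2r 0.0577), Neat1 null library 1 (Igf2r 0.0733, Plagl1 0.0580, Hoxa13 0.0532) or Neat1 null library 4 (Peg3 0.0761, Plagl1 0.0696).

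Markers of cell types divided. Pdgfra, the platelet-derived growth factor receptor of fibroblasts, fell from 90.0 ± 57.0 to 7.50 ± 2.91 CPM (log2 fold change -3.59, SE 0.51, adjusted p = 0.00806; without Neat1 null library 3, -3.36, adjusted p = 0.0646), and S100a4 rose by 2.08 (SE 0.68), by 0.61 without Neat1 null library 1 (adjusted p = 0.353). These were the called members of 8 tested fibroblast markers (3 adjusted over the list alone, list adjusted p = 0.459). Of 7 neural and glial markers 2 fell (3 adjusted over the list alone, list adjusted p = 0.180), the myelin gene Mbp by 1.86 (SE 0.59) and the microtubule protein gene Map2 by 1.39 (SE 0.45). Of 2 tested markers of myeloid and other blood cells the lysosomal gene Cd68 fell by 2.47 (SE 0.64), 2 passing adjusted over the list alone. Tnnt1 was the called member of 3 muscle markers (1 adjusted over the list alone, list adjusted p = 0.478). None of 8 epithelial, 4 endothelial and 4 cartilage, bone and fat markers passed over all genes or adjusted over the list alone (0 each), with list adjusted p-values of 0.334, 0.478 and 0.354. Of the sex-linked genes the Y-linked Ddx3y, Kdm5d and Eif2s3y were called higher in Neat1 null libraries (3 of 4 tested, 4 adjusted over the list alone, list adjusted p = 0.315). They had 35.8 ± 28.9, 20.4 ± 18.2 and 35.6 ± 29.5 CPM against at most 0.463 CPM in any wild-type library. The list was called without Neat1 null library 3 (adjusted p = 1.46e-06). X-linked Xist had 1203 ± 619 and 60.1 ± 115 CPM. The named calls ended without wild-type library 3 (0.0718 to 0.131) or 4 (0.0704 to 0.168), except Pdgfra, and without Neat1 null library 3 (0.0646 to 0.119), except the Y-linked genes. The length and GC correction ended the calls of Mbp (-1.47, adjusted p = 0.0871), Map2 (-0.57, 0.282) and S100a4 (0.86, 0.266). Without wild-type library 4, Ddx3y, Kdm5d and Eif2s3y had log2 fold changes of 9.66, 10.03 and 10.32 against 7.90, 7.97 and 8.30, and Kdm5d had 7.35 without Neat1 null library 2. The calls of Map2, S100a4 and the Y-linked genes also ended without wild-type library 2 (0.0511 to 0.0918) or Neat1 null library 1 (0.0585 to 0.353). The call of S100a4 ended without wild-type library 1 (0.0635), those of Mbp and Eif2s3y without Neat1 null library 2 (0.0761 and 0.0513), and those of Mbp, Map2 and the Y-linked genes without Neat1 null library 4 (0.0604 to 0.0980).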

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

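The tests of gene length, library sex, histone genes and Hras1 below were chosen after the results were seen, and the count of sample splits was chosen before.

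The split by genotype was the only 1 of 35 splits of the 8 libraries into 4 and 4 to call as many genes: it called 2356, and the highest count among the other splits was 0, which argues against chance as the source of the calls. A length and GC trend as the whole cause is argued against by 1236 of the 2356 calls that remained in the same direction after each library was corrected for both. Sex cannot be told apart from genotype, with 0 male wild-type and 1 female Neat1 null library, which lay 1.46 times as far from wild-type as the male ones over 2268 autosomal calls. Those calls were chosen with that library in the fit, and 13 genes were called without it, so the 1.46 does not weigh sex against genotype. The trend with gene length followed genotype without overlap (exact permutation p = 0.0286) and may also reflect preparation or RNA from outside annotated genes, whose share had a correlation of 0.310 with the length slope within genotypes (8 libraries, exact permutation p = 0.530). Whether Neat1 loss or the sex and origin of the embryos gives most of the calls stays open, and without Neat1 null libraries 1 and 3 the list medians were 0.97 for cholesterol synthesis (0.97 with all libraries), 0.62 for cell cycle (0.53), 0.74 for oxidative phosphorylation (1.65) and 2.23 for histones (3.67).

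Histone genes had a median log2 fold change of 3.67 (SD 0.69 over 12 genes) before and 2.84 (SD 0.73) after the length and GC correction. These SDs are spreads between genes, not between libraries. With smaller folds after the correction, 6 of the 12 calls ended and 6 remained. The trend is argued against as the whole cause for the 6 that remained. The list has a median exon length of 788.5 bases, against 4457 for all tested genes. How well the correction holds for such short genes was not checked. A larger share of cells in S phase was not decided as a cause. The other 15 S-phase genes of the cell cycle list had a median of 0.75 (SD 0.58) with 2 called. That lies below the histone median, but the test assumed that both groups rise equally with S phase, which was not checked. More RNA without poly(A) tails in the Neat1 null libraries stays open: Rn45s, Rmrp and Rpph1 had log2 fold changes of 3.15, 3.40 and 3.88 (median 3.40), with adjusted p-values of 0.0452, 0.0597 and 0.0780. The rise of Rn45s rests on Neat1 null library 1 (5.23% of counts), as the other Neat1 null libraries (0.457% to 0.596%) lie within the wild-type range (0.138% to 0.939%), while the histone median was 2.63 without that library.

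Hras1 had a log2 fold change of 2.09 (SE 0.56) after the length and GC correction against 2.26 (SE 0.53) before, which argues against the trend as the whole cause. Higher Ras-ERK output was not decided: the median log2 fold change of its 27 feedback and target genes was -0.32. A bootstrap that resampled these genes, not the libraries, gave a 95% interval of -0.90 to 0.03. That interval leaves out the spread between libraries. The list median lay between -0.54 and -0.18 with any 1 library left out. Differing expression of the HRasV12 construct between the cultures was not tested.

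Single libraries stood apart from the other 3 of their group, by a gap divided by the group's range above the critical value of Dixon's test for 4 samples, in 10 of 178 groups checked (5.62%, where chance gives about 5%). In Neat1 null library 1 these were Hist1h1e (ratio 0.894), S100a4 (0.832) and the Rn45s share (0.971), all high, with Hist1h1e at 4.33 on the log2(CPM + 1) scale against 0.81 to 1.18 in the others. In Neat1 null library 3, Csrp1 (0.927), Pfkl (0.921) and Fdps (0.957) were high. Wild-type library 1 was low for Eno2 (0.857) and Cd68 (0.830), wild-type library 3 was low for Tpi1 (0.848), and wild-type library 4 was high for Eif2s3y (0.834), at 0.45 on the log2(CPM + 1) scale against at most 0.07. Reads ambiguous between genes, outside the tested counts, averaged 1.52% of reads in Neat1 null and 1.15% in wild-type libraries (exact permutation p = 0.0286, adjusted 0.0408 over 10 measures).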

How the results depend on the processing

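The length and GC correction, the sex covariate and the fit without Neat1 null libraries 1 and 3 were chosen after the data were seen, and the other alternatives before. Neat1 expression kept its direction in each alternative and was called in each but the fit without Neat1 null libraries 1 and 3 (log2 fold change -6.34, adjusted p = 0.0899, against at most 0.0232 in the others), which has fewer samples. Its log2 fold change ranged from -6.77 to -5.93 with 1 library left out. The Neat1 mean difference of log2(CPM + pseudocount) was -5.91 with a pseudocount of 1 and -6.07 with 0.1 (exact permutation p = 0.0286 in both). The number of differentially expressed genes, 2356, ranged from 11 to 2965 with 1 library left out (higher in Neat1 null 1 to 1708, lower 6 to 1388), was 3590 with DESeq2 (1630 lower, 3698 genes without an adjusted p). It was 7 at an adjusted p under 0.01 (1 higher, 6 lower) and 7 without Neat1 null libraries 1 and 3 (5 higher, 2 lower), where 5 of the original calls remained. It fell to 18, 11 and 13 without wild-type library 3, wild-type library 4 and Neat1 null library 3. At an unadjusted p under 0.05 there were 4789 genes. With the length and GC correction 647 genes were lower, and with the sex covariate 1595. The sex covariate kept 1368 of the 2356 calls, and 28 of 80 other named genes lost theirs. The replicate numbers do not pair the samples: same-numbered libraries had deviations correlated at 0.317, -0.258, -0.0140 and 0.107, and 1 of 4 libraries matched its own number best. With the replicate number as a block 2245 genes were called. The number of called gene lists, 5, ranged from 4 to 9 with 1 library left out. It was 8 without a low-count filter and with the length and GC correction. It was 9 with 1 surrogate variable and without Neat1 null libraries 1 and 3, and 0 with an estimated correlation and with fry. Of 80 other named genes, 56 kept their side of the threshold with the length and GC correction and 24 lost the call. With the sex covariate 4 reversed: Nr4a1 (log2 fold change -0.16), Ddx3y (-1.01), Kdm5d (-4.48) and Eif2s3y (-4.94). These values follow from Neat1 null library 3, which alone sets the genotype difference in that fit. Nr4a1 had 26.2 CPM there against a wild-type mean of 29.3 CPM. Ddx3y had 0.071 CPM there, and Kdm5d and Eif2s3y had 0. For the other changes the cause was not tested. The planned sex covariate was not run as planned, because its condition of both sexes in both groups was not met. With 4 libraries per group, changes of 2-fold were mostly not detectable.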

Other observations

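The gene groups and the chromosome medians in this part were chosen after the data were seen, and the test of genes near Neat1 before.

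Of 77 cytosolic ribosomal protein genes 53 rose and 0 fell (median log2 fold change 1.85), of 76 mitochondrial ribosomal protein genes 48 rose (1.54), and of 37 proteasome subunit genes 20 rose (1.43). The proteasome subunits Psmb5 and Psma7 rose by 2.49 (SE 0.47) and 2.65 (SE 0.54), and the mitochondrial ribosomal protein gene Mrpl54 by 2.67 (SE 0.55). The metallothionein genes Mt1 and Mt2 rose by 2.49 (SE 0.59) and 2.54 (SE 0.45), 2 of 3 tested. After the length and GC correction 20, 35 and 15 genes of the first 3 groups rose. All 4 groups had an adjusted p of 0.140 with an estimated correlation.

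Of 15 GABA and glutamate receptor genes 9 fell and 0 rose (median -2.25), the glutamate receptor gene Gria4 by 7.97 (SE 1.11), and of 14 voltage-gated channel genes 8 fell (median -2.74), the sodium channel genes Scn1a and Scn9a by 3.90 (SE 0.66) and 2.85 (SE 0.61). Of 35 protocadherin genes 6 fell, Pcdh7 from a mean of 95.4 to 25.9 CPM. The growth factor genes Fgf10, Fgf13 and Fgf11 fell by 4.09 (SE 0.68), 2.70 (SE 0.69) and 2.30 (SE 0.61), 3 of 7 tested, while among 11 Wnt genes Wnt11 rose by 1.42 (SE 0.42) and Wnt16 fell by 3.53 (SE 0.90). After the length and GC correction 7, 3, 5 and 3 genes of the first 4 groups fell. The adjusted p with an estimated correlation was 0.140 for these groups and 0.684 for the Wnt genes.

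Genes within 10 Mb of Neat1 were called in 43 of 219 cases (19.6%, 34 higher and 9 lower), and genes elsewhere in 17.7% (odds ratio 1.14, 95% interval 0.794 to 1.6, Fisher's exact p = 0.423). Whether variants linked to the targeted locus add to calls there may not be told from this odds ratio of 1.14. The first part of chromosome 19, which holds Neat1, stood high in Neat1 null library 3 alone of the Neat1 null libraries. Its median log2 deviation after the length and GC correction was 0.595 there and -0.281 to -0.0179 in the others.

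After the length and GC correction, genes of chromosome 14 had median log2 deviations of -0.377 in wild-type library 2 and -0.367 in wild-type library 4, and of 0.197, 0.343 and 0.307 in Neat1 null libraries 2, 3 and 4, each outside the range of 1000 random gene sets of the same size and of the same sign in both parts of the chromosome. In the other 3 libraries it lay between -0.0796 and 0.0266, within that range. Chromosome 19 had medians of 0.318 in Neat1 null library 3 (0.595 in its first and 0.116 in its second part) and -0.344 in Neat1 null library 4 (-0.281 and -0.383). In wild-type libraries 1 to 4 they were -0.114, 0.141, -0.190 and 0.231, also outside the random range. Of 152 pairs of autosome and library, 6 had a median beyond 0.3 and 61 lay outside the random range. Chromosome X had medians of 0.0893 to 0.289 in the 4 wild-type libraries, all outside the random range, and of -0.387, -0.0678, -0.326 and -0.102 in Neat1 null libraries 1 to 4, all but that of library 2 outside it.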
